A study of Caenorhabditis elegans and Caenorhabditis briggsae with 26 samples.

How the data were processed

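The series holds poly(A)-selected RNA sequencing libraries of the nematodes Caenorhabditis elegans (wild-type strain N2) and Caenorhabditis briggsae (wild-type strain AF16), grown at 20 °C on bacteria in liquid medium. Per the labels' protocols, embryos were isolated from adults with bleach, part of them hatched without food into arrested L1 larvae, and later stages were collected at fixed hours after food was added. These were 7, 20, 29, 41, 52 and 57 h in C. elegans and 6, 20, 28, 41, 53 and 63 h in C. briggsae for the larval stages L1 to L3, L4 early and late in the stage, and young adults not yet carrying eggs. The time course was run again as culture B. In each species embryos and L1 larvae had 3 libraries, of which A1 and A2 were libraries of culture A, so these stages had n = 2 cultures. The other 5 stages had 1 library of culture A each, and a mixture of all stages served as a reference sample with 2 libraries. The labels state that A and B were separate time courses; A1 and A2 are replicates of the same sample, and their spread may be technical.

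The deposited values are RPKM, reads scaled by gene model length and by mapped reads, computed by the authors for 21774 C. elegans gene IDs in 26 libraries. Reads were aligned with BWA 0.5.7, per the submitters' processing notes. The genome build, gene annotation, counting rule, treatment of reads with several hits and source of the ortholog assignment are not given in the sources used here. C. briggsae values stand under the ID of the C. elegans ortholog in the deposited table: 13938 IDs had them, 7836 had none, and 125 that shared identical C. briggsae values with another ID were left out, which left 13813 ortholog pairs. No RPKM value in the deposited table equals 0, and the lowest values fall on steps, so a value near the bottom of the scale is a floor and not a measured level. Values were used as deposited, with no further scaling.

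Read counts were not used here and RPKM sums do not give depth. Among 1261 C. elegans genes at their lowest step, 287 (22.8%) lay within 3% of the step that 1 read would give in the young adult library at 25200000 mapped reads, taking exon lengths from Ensembl 115. This is an estimate of depth that rests on those lengths. The lowest steps of the C. elegans libraries fell into separate sets: relative to young adults the step was 1.10 times as high in embryo library A1 and 1.02 to 1.17 times in L2 to late L4, but 2.73 and 2.89 times in embryo libraries A2 and B and 2.87 to 3.97 times in the L1 libraries. A higher step means fewer reads behind a low value, so low-abundance transcripts were measured less precisely in the L1 libraries and in embryo libraries A2 and B. Sums of RPKM ran from 616331 to 814470 in C. elegans and from 516091 to 667794 in C. briggsae.

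Coordinates came from the Ensembl 115 annotation of WBcel235, matched by sequence name. Gene symbols came from RefSeq, matched by locus tag, and otherwise from a list of gene names. By a match to Ensembl or a RefSeq symbol 18743 IDs were matched. Another 3031 were not, 2643 of which start with RIT. Coordinates are those of the C. elegans gene in both species. Families of near-identical copies, such as vitellogenins, major sperm proteins, histones, the abu genes and mlc-1 with mlc-2, share reads, and the split between their members is uncertain.

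Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(RPKM + 1), which understates the change of low genes. The libraries of a culture were averaged on that scale first. Genes with at least 1 RPKM in at least 2 of the samples compared were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Embryo versus L1 was fitted per species on cultures A and B, and the species difference in that change as an interaction over 8 cultures. Stages were compared across both species by an additive model of species and stage on culture A of the 7 stages, 14 samples with 6 residual degrees of freedom, in which the species serve as the replicates of a stage. Here a change that runs opposite ways in the species counts as error. RPKM means ± SD are over the cultures. Spearman correlations between stages of the species ran across ortholog pairs, with an exact one-sided permutation of the stage labels, and Pearson correlations of the 7-stage profile used pairs with a range of at least 2 on the log2 scale in both species. Correlations are across genes, which are not independent replicates. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the figures.

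The samples in each fit, the 22 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except alternatives said to have been added later. The lists are vitellogenins, major sperm proteins, spermatogenesis, oocyte and maternal factors, germline, cell cycle and replication, embryonic transcription factors, cuticle collagens, molting, heterochronic genes, body wall muscle, pharynx, neuronal, intestine, histones, ribosomal proteins, argonautes, heat shock and stress, fasting and glyoxylate cycle, Hox genes, vulva and gonad, and translation and RNA polymerase housekeeping. Lists with at least 4 measured members were tested by camera with an inter-gene correlation preset of 0.01, and again with the correlation estimated from the data. With the estimate, camera takes its degrees of freedom from the residuals of the fit, which are few with n = 2 cultures per stage. That version therefore had little power, and its adjusted p cannot decide whether a list holds. The estimates themselves ran from -0.0991 (Hox genes) to 0.865 (ribosomal proteins), both in C. elegans, and most lay above the preset. Where members of a list correlate more than the preset, its camera p is too small, so the preset adjusted p values cannot decide this alone either. Named genes are the 8 largest rises and falls per species between embryo and L1 among called genes with a symbol and at least 10 RPKM, the 2 most changed called members of each list, 5 species differences per direction, 4 rises and falls per successive stage, the 2 members of a list with the highest stage values, the 5 lowest profile correlations, and all vitellogenins and heterochronic genes. The lowest profile correlations were taken among pairs with a log2 range of at least 3 in both species. Genes chosen outside this rule are said to be so. List counts were also adjusted over the list alone.

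The culture letter pairs embryos with L1 larvae, because the labels put each letter in a single time course. Deviations from the group means, embryo against L1 of the same letter, correlated across genes at -0.0112 in C. elegans and 0.195 in C. briggsae. The fit without the pairing is reported and the blocked fit was an alternative. On simulated data built on the C. elegans embryo and L1 libraries, with 200 of 15277 genes changed, 47.8% of 2-fold, 98.5% of 4-fold and 98.5% of 16-fold changes were recovered, and 17 of 180 calls were unchanged genes (1.51% of calls where as many genes were changed as were called in the data). In C. briggsae recovery was 8.96%, 91.0% and 100% at those sizes, for the species difference 1.49%, 76.1% and 97.0%, for young adult versus late L4 0%, 23.9% and 84.8%, and for L2 versus L1 0%, 25.4% and 81.8%. With 200 genes changed, unchanged genes made up 6.45% to 12.2% of the calls over these 5 comparisons. The 1.51% came from a simulation that took the called genes and their fitted changes as the truth. Noise was drawn independently for each gene, so false calls from shifts shared by many genes of a culture or library were not assessed. Alternatives varied the pseudocount (0.1 and 5), the RPKM minimum (none and 5), the scaling (quantile normalization and median-ratio), the pairing, the treatment of libraries A1 and A2, the trend, the culture left out and the gene families kept. The reference mixtures entered no comparison between stages.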

Results

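Transcript levels were measured across the life cycle of the nematodes C. elegans and C. briggsae in 13 libraries per species. Embryos and L1 larvae had 2 cultures each (3 libraries), L2, L3, L4, late L4 and young adult animals 1 library each, and a mixture of all stages 2 libraries. The values are RPKM as the authors computed them, and their read depth is unknown apart from an estimate for the C. elegans young adults. At least 1 RPKM was found for 12763 genes (58.6%) in C. elegans young adults, the lowest count, and for 15398 genes (70.7%) in reference library A2. In C. briggsae the count ran from 8586 orthologs (61.6%) in embryo library B to 11753 (84.3%) in reference library A2.

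Replicate libraries differed to unequal degrees. In C. elegans embryos, libraries A1 and A2 of the same culture differed by more than 2-fold in 16.13% of 14120 genes, while A2 and B differed so in 1.56%. Library A1 held more RNA of short genes than A2: the median log2 difference was 0.95 over 435 genes under 500 bases, 0.97 over ribosomal protein genes and -0.45 over 2576 genes of at least 2000 bases. The 100 most abundant genes took 28.4% of the RPKM sum in A1, 17.4% in A2 and 17.9% in B. C. briggsae embryo cultures A and B also stood apart, with 14.1% (A1 against B) and 13.4% (A2 against B) of genes beyond 2-fold. L1 pairs ranged from 1.66% to 10.5% in C. elegans and from 0.232% to 6.55% in C. briggsae.

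The comparison of embryos with L1 larvae asked which transcripts differ across hatching and first feeding. Among the 8 largest differences per direction in C. elegans, 4 collagen genes and a cuticlin gene were higher in embryos and 3 cathepsin B-like protease genes higher in L1 larvae, while the collagen list as a whole went both ways. The cuticle collagen dpy-14 (H27M09.4, chromosome I, 6843589 to 6845142 in WBcel235) reached 2994 ± 436 RPKM in embryos and 5.39 ± 1.37 RPKM in L1 larvae (SD, n = 2 cultures each; log2 difference 8.88 ± 0.24 SE, adjusted p = 3.14e-06). The collagens dpy-17 (F54D8.1, III, 5107330 to 5108492; 3051 ± 338 against 6.04 ± 1.67 RPKM) and sqt-3 (F23H12.4, V, 12352745 to 12354320; 2772 ± 127 against 5.79 ± 1.18 RPKM) followed at 8.78 and 8.68. Next were ttr-50, of the transthyretin-related family (8.58), dbd-2 (8.19), the cuticlin cut-2 (7.93), col-165 (7.77) and the hatching protease gene hch-1 (7.55). Lower in embryos were pud-3 (F15E11.15, V, 2324634 to 2325152), at 0.494 ± 0.226 against 704 ± 2.43 RPKM (-8.89 ± 0.22, adjusted p = 3.14e-06), and the pharyngeal gland gene phat-7 (-8.84). Genes for cathepsin B-like gut proteases fell too, with cpr-4 (F44C4.3, V, 6614674 to 6615851) at 3.75 ± 3.08 against 1863 ± 314 RPKM (-8.78), cpr-5 at -8.12 and cpr-1 at -7.99. The remaining largest falls were spig-11 (-7.86), hrg-7 (-7.68) and nspc-16 (-7.49).

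Of 15277 C. elegans genes tested with limma, 10821 differed, 6501 higher and 4320 lower in embryos (11168 at unadjusted p under 0.05). A difference of at least 2-fold held for 5187 of the higher and 3638 of the lower genes. The median gene lay 0.33 above 0, and quantile normalization and median-ratio scaling moved that median by -0.27 and -0.32. The split between directions moved with it, to 5649 higher and 5314 lower under quantile normalization and 5459 higher and 5727 lower under median-ratio scaling. The libraries differed in composition as described above, and without embryo library A1, an alternative added after seeing the data, 11470 genes were called. Without embryo culture B the split was 3851 higher and 3988 lower, and without L1 culture A 6227 and 2629.

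Oocyte, germline and cell division genes were higher in C. elegans embryos. Of 35 measured oocyte and maternal factors 33 were higher, 1 lower and 1 not called (33 and 1 adjusted over the list alone), led by the cytoplasmic RNA-binding proteins pos-1 (6.74 ± 0.22 SE; 325 ± 0.248 against 2.08 ± 0.515 RPKM) and mex-5 (6.00 ± 0.24). That list's camera test gave adjusted p = 3.47e-09 and adjusted p = 0.398 with an estimated correlation. The translational regulators gld-1 (4.56 ± 0.24) and gld-3 (3.89 ± 0.25) led the germline list, with 29 of 33 higher and 0 lower (30 adjusted over the list alone; camera adjusted p = 1.24e-05, adjusted p = 0.506 with an estimated correlation). All 49 cell cycle and replication genes were higher, also when adjusted over the list alone, among them the B-type cyclins cyb-1 (5.13 ± 0.25) and cyb-3 (4.82 ± 0.23; camera adjusted p = 4.20e-11, adjusted p = 0.398 with an estimated correlation). Among 38 embryonic transcription factors 33 were higher and 1 lower (the same counts adjusted over the list alone), with hnd-1 at 5.35 ± 0.26 and the T-box gene tbx-11 at 4.82 ± 0.25 (camera adjusted p = 5.13e-07, adjusted p = 0.398 with an estimated correlation). Histones had 66 of 75 higher and 2 lower (66 and 2 adjusted over the list alone), with the linker histones hil-7 at 5.39 and hil-4 at 3.97 (camera adjusted p = 2.14e-08, adjusted p = 0.506 with an estimated correlation). Poly(A) selection captures most core histone transcripts poorly. Molting genes split 32 higher and 4 lower of 42 (32 and 5 adjusted over the list alone), led by cut-2 and hch-1 (camera adjusted p = 6.34e-05, adjusted p = 0.506 with an estimated correlation).

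Intestinal genes were lower in C. elegans embryos in 35 of 41 cases and higher in 0 (36 lower adjusted over the list alone; median log2 difference -3.42), with cpr-4 and cpr-5 in front (camera adjusted p = 5.90e-13, adjusted p = 0.398 with an estimated correlation). Neuronal genes fell in 37 of 51 cases and rose in 2 (37 and 2 adjusted over the list alone), with the neuropeptide gene flp-14 at -5.51 ± 0.35 and the neuropeptide-processing enzyme egl-21 at -4.61 ± 0.27 (camera adjusted p = 2.36e-08, adjusted p = 0.567 with an estimated correlation). Ribosomal protein genes were lower in 58 of 60 cases (59 adjusted over the list alone; median -1.63), for example rpl-6 (-1.96 ± 0.28) and rpl-3 (-1.94 ± 0.28), with camera adjusted p = 4.28e-12 and adjusted p = 0.567 with an estimated correlation. Under quantile normalization their median was -0.49 and 21 of 60 fell. Fasting and glyoxylate cycle genes fell in 13 of 22 cases and rose in 5 (13 and 5 adjusted over the list alone), with the lipase lipl-1 at -4.62 and the acyl-CoA synthetase acs-2 at -3.53 (camera adjusted p = 0.0210, adjusted p = 0.567 with an estimated correlation). That list lost its camera call without embryo culture A or B (adjusted p = 0.0637 and 0.0936).

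The remaining C. elegans lists gave no camera call with the preset correlation and all cultures kept. With a culture left out, body wall muscle, argonaute and collagen genes gained a call in some fits. Spermatogenesis genes had 5 of 9 higher and 1 lower, led by spe-27 (5.58 ± 0.24). Collagens split 15 higher and 18 lower of 36, with a median of -0.75, a mean of 0.20 and a test direction down. Heterochronic timing genes had 8 of 14 higher and 3 lower, with the zinc-finger gene hbl-1 at 4.65 ± 0.25 and lin-41 at -3.66 ± 0.25. Body wall muscle genes had 6 of 41 higher and 16 lower, with the troponin I genes tni-3 at -3.14 and unc-27 at -2.76. Pharynx genes split 12 higher and 8 lower of 20 (phat-6 -5.89, marg-1 -5.41), argonautes 10 and 2 of 16 (wago-1 3.38, alg-5 2.97), and vulva and gonad genes 13 and 8 of 22 (hlh-2 2.76, nlp-7 -2.62). Among heat shock and stress genes 7 of 21 were higher and 4 lower, with the small heat shock gene sip-1 at 4.77 and hsp-4 at 2.64. Their median was 0.20 but the test direction was down, and the counts turned to 4 and 5 under quantile normalization and to 3 and 4 under median-ratio scaling, where the median was -0.12. Hox genes had 3 of 5 higher, with ceh-13 at 1.58 and egl-5 at 0.86, and translation and RNA polymerase housekeeping genes split 10 and 7 of 26 (13 and 3 under quantile normalization, 6 and 8 under median-ratio scaling), with iff-1 at 4.16 and gpd-1 at 4.11. The egl-5 call was lost under 4 of the alternatives, where its adjusted p ran from 0.0528 to 0.164. Adjusted over the list alone these counts were 5 and 1, 16 and 19, 8 and 3, 6 and 15, 12 and 8, 10 and 2, 13 and 8, 6 and 4, 2 and 0, and 10 and 7, in the order given.

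**Figure D1:**
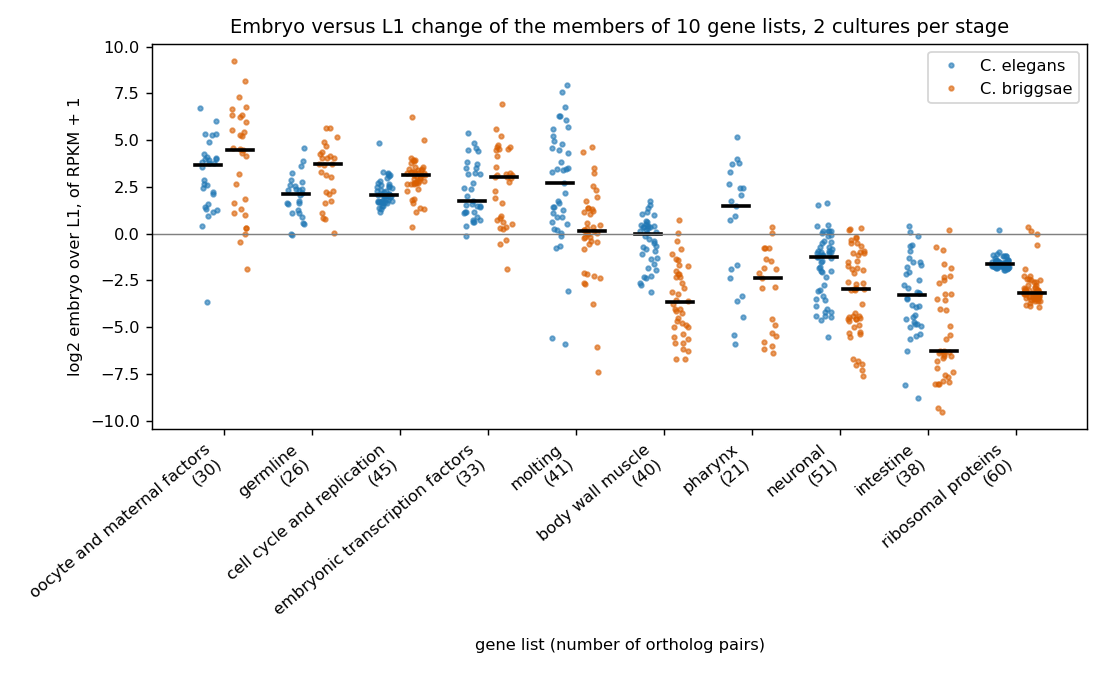
Each point is a gene of the named list, placed by its log2 difference of RPKM + 1 between embryos and L1 larvae (mean of 2 cultures per stage), in C. elegans (blue) and C. briggsae (orange); black bars are medians over the ortholog pairs, whose number stands in parentheses. Muscle genes sit near 0 in C. elegans (median -0.04) and well below it in C. briggsae (-3.68), and ribosomal protein genes sit at -1.63 and -3.16.

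Among the 8 largest differences per direction in C. briggsae, mex-5 and cpg-1 of the oocyte and maternal list were higher in embryos, and 3 cathepsin B-like protease, 2 aspartyl protease and 2 collagen genes higher in L1 larvae. The largest rise was that of mex-5 (C. elegans ID W02A2.7, IV, 13353723 to 13356104), at 1416 ± 440 RPKM in embryos and 1.49 ± 1.17 in L1 larvae (SD, n = 2 cultures; 9.20 ± 0.40 SE, adjusted p = 9.97e-05). The Skp1-related genes skr-7 (9.11), skr-8 (9.05) and skr-15 (8.90), the C-type lectins clec-87 (8.53) and clec-88 (8.48), ttr-50 (8.41) and the eggshell chondroitin proteoglycan cpg-1 (8.13) followed. Lower in embryos were cpr-5 (W07B8.5, V, 1132598 to 1134036), at 1.23 ± 0.998 against 1551 ± 19.7 RPKM (-9.52 ± 0.33, adjusted p = 9.29e-05), cpr-4 (-9.32) and cpr-9 (-8.88). The aspartyl proteases asp-17 (-9.08) and asp-15 (-8.75), the collagens col-160 (-8.98) and col-94 (-8.54), and nspc-20 (-8.84) fell as well.

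Of 11891 C. briggsae genes tested, 8835 differed, 3906 higher and 4929 lower in embryos (9044 at unadjusted p under 0.05), and 279 of the higher and 821 of the lower genes changed by at least 16-fold. Quantile normalization moved the median gene by 0.29 from -0.14 and turned the split to 4697 higher and 3897 lower. Median-ratio scaling moved it by 0.16. Without L1 culture A 9614 genes were tested and without L1 culture B 9681, as genes detected only in L1 larvae no longer passed the filter of 2 cultures. The calls fell by more than the genes tested, so the filter explains at most part of that drop. Most of the calls left were higher in embryos.

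Cell cycle and replication genes were higher in C. briggsae embryos in 44 of 45 cases (44 adjusted over the list alone), with cyb-3 at 5237 RPKM in embryos and 68.2 in L1 larvae (6.25 ± 0.14) and the replication helicase subunit mcm-7 at 5.01 ± 0.19 (camera adjusted p = 1.36e-14, adjusted p = 0.503 with an estimated correlation). Oocyte and maternal factors rose in 25 of 30 cases and fell in 1 (25 and 1 adjusted over the list alone; camera adjusted p = 4.28e-08, adjusted p = 0.503 with an estimated correlation). Germline genes rose in 24 of 26 cases (24 adjusted over the list alone), with gld-1 and gld-3 both at 5.64 (camera adjusted p = 1.78e-08, adjusted p = 0.503 with an estimated correlation). Embryonic transcription factors had 25 of 33 higher and 1 lower (25 and 1 adjusted over the list alone), with the T-box genes tbx-9 and tbx-37 in front, the former at 6.92 ± 0.24 (camera adjusted p = 2.17e-07, adjusted p = 0.503 with an estimated correlation). Histones had 16 of 25 higher and 1 lower (16 and 1 adjusted over the list alone), with the variant H2A gene htz-1 at 3.63 and the linker histone hil-1 at -4.13 (camera adjusted p = 0.00368, adjusted p = 0.619 with an estimated correlation). Argonautes rose in 7 of 13 cases and fell in 2 (7 and 2 adjusted over the list alone), with ppw-2 at 4.61 and sago-2 at 3.96 (camera adjusted p = 0.0437, adjusted p = 0.619 with an estimated correlation). The argonaute list lost its camera call without L1 culture A or B (adjusted p = 0.205 and 0.118), and the histone list without L1 culture B (adjusted p = 0.172).

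Ribosomal protein genes were lower in C. briggsae embryos in 57 of 60 cases (57 adjusted over the list alone; median -3.16), with rpl-15 at 200 ± 3.69 against 3039 ± 105 RPKM (-3.92 ± 0.11) and rpl-30 at -3.88 ± 0.12 (camera adjusted p = 3.89e-16, adjusted p = 0.503 with an estimated correlation). Intestinal genes fell in 35 of 37 cases (35 adjusted over the list alone; median -6.29; camera adjusted p = 8.12e-09, adjusted p = 0.503 with an estimated correlation). Neuronal genes fell in 42 of 47 cases (42 adjusted over the list alone), with the neuropeptide gene flp-1 at -7.62 ± 0.49 and egl-21 at -7.30 ± 0.38 (camera adjusted p = 4.16e-08, adjusted p = 0.503 with an estimated correlation). Body wall muscle genes fell in 37 of 40 cases and rose in 1 (37 and 1 adjusted over the list alone), with the myosin light chain genes mlc-2 at -6.72 ± 1.15 and mlc-1 at -6.70 ± 1.15 (camera adjusted p = 5.48e-06, adjusted p = 0.619 with an estimated correlation). Pharynx genes fell in 14 of 21 cases (14 adjusted over the list alone), with the troponin tni-4 at -6.39 ± 1.04 and the myosin myo-1 at -6.19 ± 0.74 (camera adjusted p = 0.00695, adjusted p = 0.619 with an estimated correlation). Under quantile normalization 9 pharynx genes were lower and 1 higher, with a median of -1.45. Muscle and pharynx transcripts also differed between the embryo cultures, with medians 1.56 (40 genes) and 1.42 (21 genes) higher in library A2 than in B.

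The other C. briggsae lists gave no camera call with the preset correlation, the values as deposited and all cultures kept. With a culture left out, heterochronic, collagen, heat shock and stress, and fasting and glyoxylate cycle genes gained a call in some fits. Under quantile normalization 14 lists were called, with spermatogenesis (up, adjusted p = 0.0245), heterochronic (down, adjusted p = 0.0124) and fasting and glyoxylate cycle genes (down, adjusted p = 0.0245) in addition. Collagens split 12 higher and 23 lower of 40, with col-160 and col-117 (-8.38) in front, and molting genes 11 and 8 of 37 (grd-13 -7.41, grd-3 -6.05) with a median of 0.15 and a mean of -0.03. Under quantile normalization 18 molting genes were higher and 9 lower, with a median of 1.04. Heterochronic genes fell in 8 of 13 cases and rose in 0, with lin-14 at -4.76 ± 1.01 and the nuclear receptor daf-12 at -3.47 ± 0.28. Spermatogenesis genes had 6 of 11 higher and 1 lower, with the RNA-binding protein gene cpb-1 at 5.31 and spe-6 at 3.94; in C. elegans cpb-1 stood at 1.74. Heat shock and stress genes split 4 and 10 of 17 (sip-1 5.28, hsp-43 -4.38), fasting and glyoxylate cycle genes 3 and 12 of 19 (the aldolase aldo-1 -6.50, dod-6 -6.12) and Hox genes 1 and 3 of 5 (lin-39 -2.38, ceh-13 2.27). Vulva and gonad genes had 6 of 21 higher and 10 lower, with nlp-7 at -4.83, nlp-2 at -3.72, a median of 0.15 and a mean of -0.38, and had 8 higher and 6 lower under quantile normalization and 9 and 9 under median-ratio scaling. Translation and RNA polymerase housekeeping genes split 12 and 7 of 20, with the calsequestrin csq-1 at -5.14 and iff-1 at 4.56. Adjusted over the list alone the counts were 12 and 23, 10 and 8, 0 and 8, 6 and 1, 4 and 10, 3 and 12, 1 and 3, 7 and 10, and 12 and 7, in the order given. Among major sperm proteins, too few of which were measured for a list test, msp-40 (0.93 ± 0.18; 1.91 against 0.527 RPKM) and msp-53 (0.71 ± 0.17) were called at low levels. Both calls were lost without either L1 culture, at adjusted p from 0.106 to 0.241, and those of lin-14 (0.0551) and lin-39 (0.0516) without L1 culture A.

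The embryo to L1 change was broadly shared between the species. Over 10722 ortholog pairs tested in both, the log2 differences correlated at Pearson r = 0.696 and Spearman rho = 0.707 across genes. Both species called 2887 pairs higher in embryos, where 1565 would be expected of independent lists, and 2793 lower, where 1402 would be expected. Of 6355 pairs called in both, 675 had opposite directions.

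The change itself was then tested for a difference between species. Most muscle, pharynx, molting and heterochronic pairs had a higher change in C. elegans than in C. briggsae, and most germline and cell cycle pairs a lower one. Of 40 body wall muscle pairs, 35 had a higher change in C. elegans and 0 a lower one (36 adjusted over the list alone), with medians of -0.04 in C. elegans and -3.68 in C. briggsae. Pharynx pairs had 18 of 21 higher and 1 lower (18 and 1 adjusted over the list alone; medians 1.46 and -2.36), molting pairs 27 of 41 and 0 (30 adjusted over the list alone; 2.69 and 0.15), and heterochronic pairs 11 of 13 and 1 (11 and 1 adjusted over the list alone; 0.82 and -1.84). Ribosomal protein pairs had 53 of 60 higher and 1 lower (54 and 2 adjusted over the list alone), with 13 and 3 under median-ratio scaling. Collagens had 27 of 45 higher and 7 lower (30 and 7 adjusted over the list alone), neuronal genes 33 of 51 and 3 (35 and 3) and intestinal genes 26 of 38 and 2 (26 and 2). Under quantile normalization the intestinal counts were 13 and 2 and the pharynx counts 12 and 1. Lower changes in C. elegans prevailed among cell cycle genes, with 28 of 45 lower and 3 higher (29 and 3 adjusted over the list alone), germline genes, with 16 of 26 and 1 (17 and 2), and oocyte factors, with 14 of 30 and 5 (14 and 5). These list counts carry no test of the list as a whole.

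Among single genes the intermediate filament gene ifa-3 (F52E10.5, X, 16267197 to 16270069) had the largest difference, at 106.5 ± 19.2 RPKM in embryos and 0.636 ± 0.130 in L1 larvae of C. elegans against 6.96 ± 3.91 and 134 ± 1.77 in C. briggsae (SD, n = 2; difference 10.20 ± 0.47, adjusted p = 3.81e-05). The cuticlin cut-2 followed at 10.05 ± 2.93 (adjusted p = 0.0225), with a C. briggsae embryo level of 169 ± 239 RPKM whose SD exceeded its mean; its call was lost in 6 of the 8 fits with a culture left out (adjusted p from 0.0510 to 0.0713). Next were grd-14 (9.26 ± 0.78), asp-15 (8.84 ± 1.40), which in C. elegans had means of 0.0813 ± 0.0235 RPKM in embryos and 0.0195 ± 0.00516 in L1 larvae, and abu-14 (8.49 ± 2.21), which lost its call without C. elegans embryo culture A or C. briggsae L1 culture A (adjusted p = 0.0528 and 0.0552). In the other direction stood pud-3 (-7.61 ± 0.71), the C-type lectin clec-50 (-7.06 ± 0.46), the homeobox gene ceh-75 (-7.05 ± 0.29), the receptor gene srd-13 (-6.95 ± 0.41) and nxnr-1 (-6.85 ± 0.52). For ceh-75 the C. briggsae embryos held 173 ± 8.01 RPKM and the C. elegans embryos 0.310 ± 0.0859. The C. elegans means of srd-13 were 0.0672 RPKM in embryos and 0.0684 in L1 larvae, near the floor. Of 12603 pairs 6299 differed, 4140 with a higher change in C. elegans and 2159 with a lower one (7189 at unadjusted p under 0.05). The split was 2700 and 3171 under quantile normalization and 3139 and 3840 under median-ratio scaling, which moved the median pair by -0.37 and -0.50.

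Across the 7 stages, 5042 of 12945 ortholog pairs differed between stages in both species together (limma F test; 6521 at unadjusted p under 0.05). Their mean level was highest in embryos for 2057 pairs (40.8%), in L1 larvae for 1150 (22.8%) and in young adults for 800 (15.9%), with 397, 204, 234 and 200 at L2, L3, L4 and late L4. Over all 12945 pairs, with no selection by that test, the same stage was highest in both species for 5197 (40.1%), where 20.3% would be expected if the species were independent. Among the 5042 pairs the share was 62.6%, but the test itself selects pairs that change alike in the species.

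Yolk genes had the largest named rises from late L4 to young adults, the step with calls among the 5 successive steps from L1 on in the model across both species. The vitellogenins, yolk proteins made by the adult intestine, rose by 11.26 ± 1.73 for vit-2 (C42D8.2, X, 5101042 to 5106169; 1.22 to 3114 RPKM in C. elegans and 0.144 to 4885 in C. briggsae; adjusted p = 0.00469), 10.82 ± 1.10 for vit-3, 10.51 ± 0.96 for vit-4 and 10.49 ± 1.52 for vit-6 (K07H8.6, IV, 8261157 to 8266459; 0.920 to 4042 and 7.85 to 8700 RPKM; adjusted p = 0.00328). In contrast vit-1 stood at 647 RPKM in C. elegans young adults and 0.331 in C. briggsae, and vit-5, with no ortholog value, at 1388 in C. elegans. The largest falls were col-176 (-8.36 ± 1.38, adjusted p = 0.00672), dbd-2 (-7.64 ± 1.45), col-117 (-7.13 ± 0.85) and col-10 (-7.05 ± 0.82). Of 12945 pairs 1072 changed, 854 up and 218 down (3234 at unadjusted p under 0.05), and without the embryo stage in the model, a setting added after seeing the data, 2332 did, 1497 up and 835 down. The falls also moved with the pseudocount, to 120 against 792 rises with a pseudocount of 5, so the share of rises depends on the setting.

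Among 32 oocyte and maternal factors 25 rose and 0 fell (28 adjusted over the list alone), among 45 cell cycle genes 26 rose and 1 fell (38 and 2 adjusted over the list alone), and among 26 germline genes 10 rose (19 adjusted over the list alone). Under quantile normalization 16 cell cycle genes rose. Spermatogenesis genes rose in 5 of 19 cases (7 adjusted over the list alone) and argonautes in 3 of 15 (6 adjusted over the list alone). Collagens changed both ways, 13 up and 21 down of 57 (14 and 26 adjusted over the list alone), and molting genes fell in 12 of 43 cases (20 adjusted over the list alone). Of 40 body wall muscle and 21 pharynx genes limma called 0, also when adjusted over the list alone. Per species, 841 pairs were higher and 1050 lower by at least 4-fold in C. elegans and 651 and 557 in C. briggsae; 383 were higher in both, where 42.3 would be expected of independent lists, and the changes correlated at r = 0.642 across genes.

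**Figure D2:**
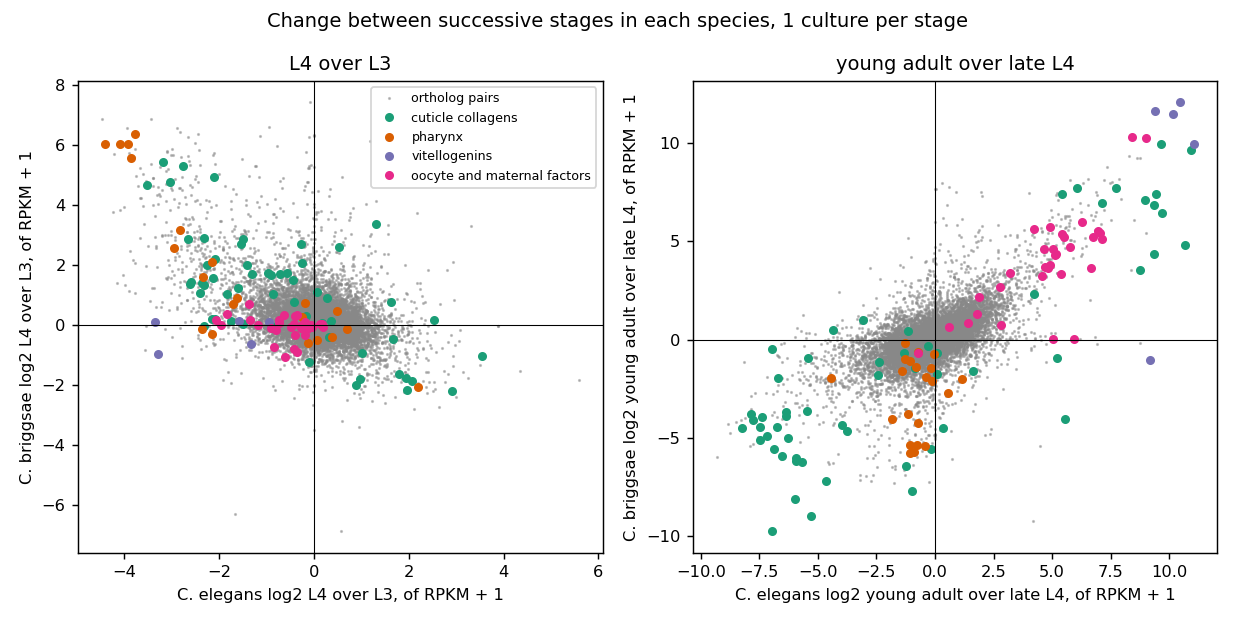
Each point is an ortholog pair, with its log2 change of RPKM + 1 in C. elegans on the horizontal axis and in C. briggsae on the vertical axis, from L3 to L4 (left) and from late L4 to young adults (right), 1 culture per stage. Of the 5 vitellogenin pairs 4 rise by at least 4-fold in both species of the young adult panel, as do 24 of 32 oocyte and maternal factors (r = 0.642 over all pairs), and the L3 to L4 changes run opposite ways (r = -0.46).

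Larval steps gave 0 calls each in limma across both species, for L2 versus L1 (576 at unadjusted p under 0.05), L3 versus L2 (413), L4 versus L3 (105) and late L4 versus L4 (251). Adjusted over the list alone, 20 of 57 cuticle collagens were higher at L2 than at L1, 2 of 43 molting genes higher and 1 lower at L3 than at L2, and 12 of 26 germline and 3 of 19 spermatogenesis genes higher at late L4 than at L4. Of the 57 collagens 23 were higher by at least 4-fold in both species, and the medians were 2.80 and 2.27. The C. elegans L1 and L2 libraries lie in separate sets of lowest steps, so in that species this step is confounded with the set. With a pseudocount of 0.1 the L2 step had 3 calls, and without the L3 stage 1. From L2 to L3 the species also disagreed: 177 pairs went opposite ways by at least 4-fold, 76 were higher and 5 lower in both, and the changes correlated at Pearson r = -0.09 and Spearman rho = 0.101. Pharynx genes had medians of 1.19 in C. elegans and -1.06 in C. briggsae at that step, while 10 of 43 molting genes were higher by at least 4-fold in both. The L4 step ran opposite ways more strongly: 337 pairs were lower and 89 higher by at least 4-fold in C. elegans, 42 lower and 480 higher in C. briggsae, and 211 went opposite ways. The changes correlated at r = -0.46 across genes, and at -0.46 and -0.47 under the other scalings. Pharynx genes had medians of -2.14 in C. elegans and 0.73 in C. briggsae at that step, and collagens -0.90 and 1.12. These single libraries have no replicate within a species.

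Levels by stage came from 1 culture per stage. The 3 major sperm protein genes with an ortholog pair had a median of 241 RPKM in C. elegans and 363 in C. briggsae young adults. In the same order msp-78 stood at 208 and 612, msp-53 at 491 and 218, and the sperm phosphatase gsp-4 at 36.9 and 78.2. Unlike these, spe-27 peaked in C. elegans embryos at 56.3 RPKM. Oocyte and maternal factors had medians of 28.4 RPKM in embryos and 134.1 in young adults of C. elegans, and of 64.7 and 85.8 in C. briggsae. The eggshell gene perm-2 reached 687 and 1583 RPKM in young adults. In C. elegans mex-5 was highest in young adults (371 RPKM), and in C. briggsae in embryos (1727, against 622 in young adults). The collagen col-117 ran from 5381 RPKM at L2 to 57.0 in C. elegans young adults and from 10619 at late L4 to 20.3 in C. briggsae, and col-10 from 2188 at L2 to 13.2 and from 8513 at late L4 to 29.4. In C. elegans cut-2 peaked at L3 (1950 RPKM), and in C. briggsae at L2 (3710) and L4 (2730), with 171 at L3 between them. The abu-6 and abu-8 genes of the pharynx list followed the same course, with abu-8 at 101 RPKM in C. elegans L3 and both at 509 in C. briggsae L2. The molting gene grd-13 was highest at L2 in both species, at 839 and 473 RPKM.

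Heterochronic genes, which set the order of larval stages, differed from each other in their courses. From embryo to late L4 lin-28 went from 111 to 10.1 RPKM in C. elegans and from 84.2 at L1 to 7.94 in C. briggsae, and lin-14 from 84.7 at L1 to 21.8 and from 97.1 to 28.4. The transcription factor lin-29 reached 31.1 RPKM at late L4 in C. elegans and 13.2 in C. briggsae, from 0.397 and 0.180 in embryos. The period-related gene lin-42 peaked at L3 in both (126 and 282 RPKM), as did lin-46 within L2 to L4 (15.5 and 16.9). In embryos hbl-1 stood at 300.4 and 28.4 RPKM, alg-1 at 148.6 and 15.3, lin-66 at 141.6 and 26.8, dre-1 at 67.1 and 7.38, nhl-2 at 58.4 and 58.9 and kin-20 at 39.3 and 26.8. The C. elegans maximum of dre-1 was 115.4 at L4. In larvae daf-12 peaked at 34.4 RPKM (L4) and 80.5 (L3), and lin-41 went from 58.9 and 73.2 at L2 to 9.84 and 8.95 at late L4. For alg-2, with C. elegans values alone, embryos held 186 RPKM.

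**Figure D3:**
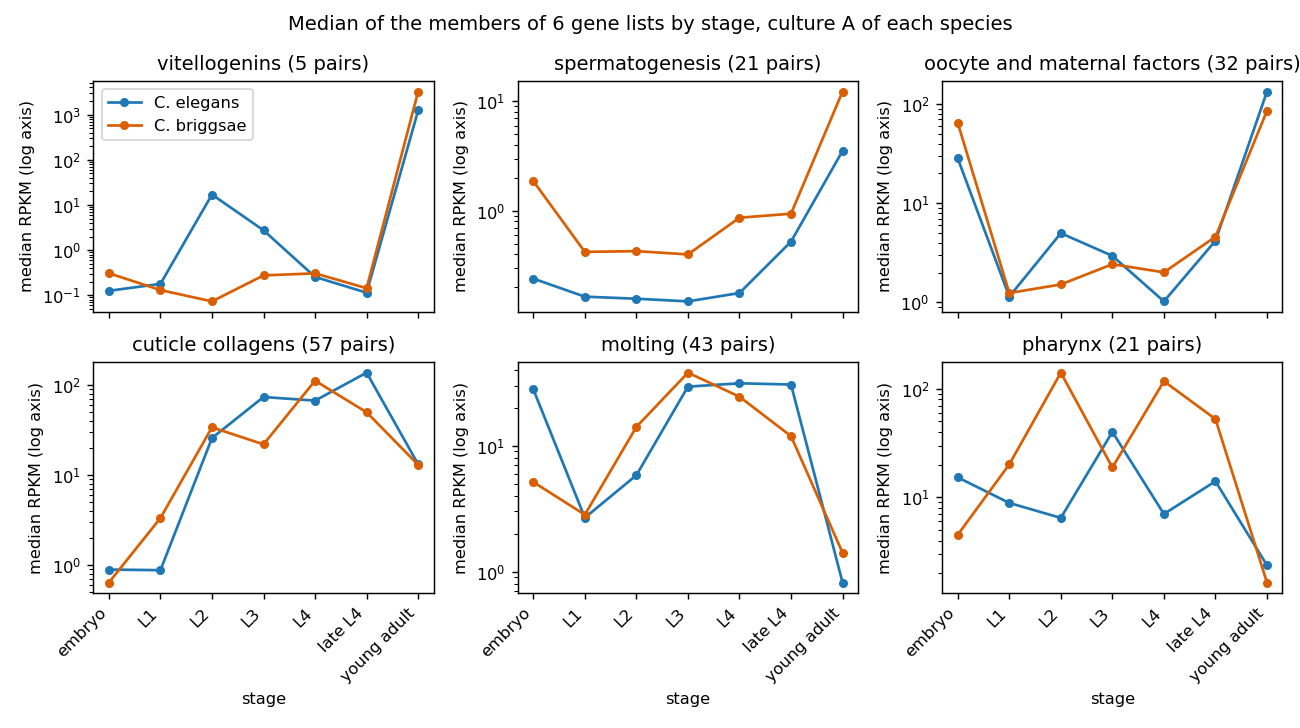
Lines give the median RPKM (log axis) over the ortholog pairs of a list at each of 7 stages in C. elegans (blue) and C. briggsae (orange), 1 culture per stage. Vitellogenins reach 1229 and 3229 RPKM in young adults, and the C. elegans L2 library holds a median of 16.99. The pharynx median peaks at L3 in C. elegans (40.04) and at L2 (141) and L4 (117.3) in C. briggsae.

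Levels averaged over the stages differed between species for 4262 of 12945 pairs, 2280 higher in C. elegans and 1982 higher in C. briggsae (5707 at unadjusted p under 0.05), and 1524 and 1210 of these by at least 2-fold. The aspartyl protease asp-1 (10.93 ± 0.74), the ribosomal protein genes rps-16 (10.57 ± 0.20; 3092 against 1.03 RPKM in L1 larvae) and rps-3 (9.17 ± 0.28), and col-144 (7.04 ± 0.47) were higher in C. elegans. The ADP/ATP carrier ant-1.2 (-10.59 ± 0.15; 0.559 against 2706 RPKM in L1 larvae), asp-15 (-9.67 ± 0.82), asp-17 (-9.10 ± 0.79) and the lysozyme lys-10 (-8.45 ± 1.04) were higher in C. briggsae. Each gene's level depends on the gene model and ortholog chosen in each species, and the design confounds these with the species.

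Libraries of the same stage resembled each other between species more than expected by relabelling. Over 12945 pairs the mean of the 7 matched Spearman rho values was 0.783 (0.744 to 0.837) and that of unmatched stages 0.654. Of all assignments of the 7 stage labels 13 gave a mean as high (exact one-sided permutation p = 0.00258; the smallest possible is 0.000198). Embryos, L1 larvae and young adults matched best in both directions. In C. elegans the L2 library was closest to C. briggsae L1 (0.796), L3 to L4 (0.796), and L4 and late L4 to L3 (0.806 and 0.801).

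**Figure D4:**
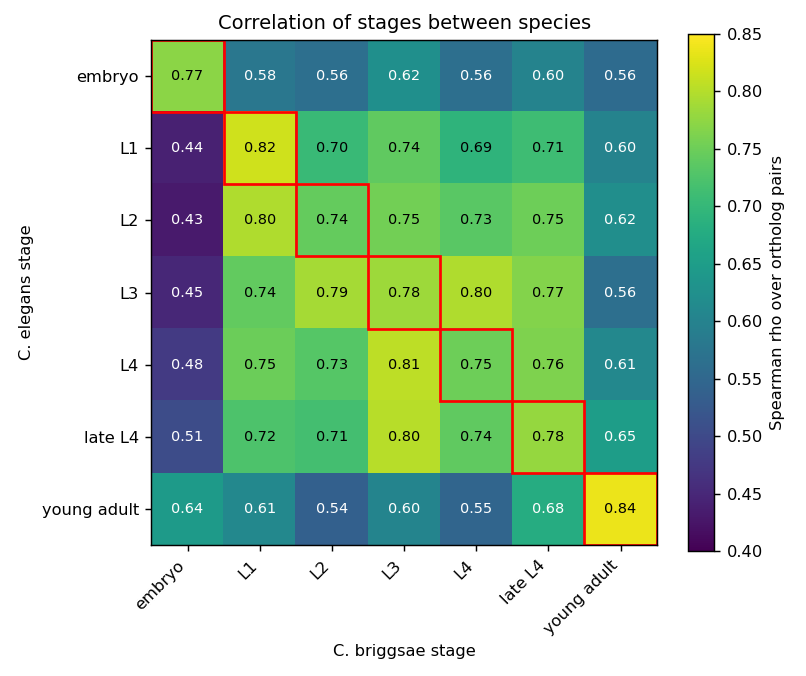
Cells give Spearman rho across 12945 ortholog pairs between each C. elegans stage (vertical axis) and each C. briggsae stage (horizontal axis), with matched stages framed in red. Matched values lie between 0.744 (L2) and 0.837 (young adults), and for L3 and L4 the highest values lie off the diagonal.

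Gene profiles over the stages were compared for 5273 pairs that varied in both species. The median Pearson r over 7 stages was 0.785 (bootstrap 95% interval over genes 0.774 to 0.793), against 0.0066 for random pairs, and 47.6% of pairs exceeded 0.8 against 11.3% at random. Embryonic transcription factors (median 0.945, 26 pairs), cell cycle genes (0.937, 40 pairs), oocyte factors (0.937, 27 pairs) and intestinal genes (0.930, 32 pairs) had high medians, and pharynx genes a low one (0.301, 20 pairs, 5 of them below 0). Of all pairs 7.04% were below 0. Among pairs with a range of at least 3 on the log2 scale in both species, Y66H1A.5 had the lowest r (-0.973). It stood at 10.1 RPKM in embryos and 90.6 in L1 larvae of C. elegans against 331 and 24.5 in C. briggsae. Next among those pairs were faxc-2 (-0.888), gst-29 (-0.887), bath-47 (-0.872) and RIT6P.965 (-0.858).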

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

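The tests of embryo age and of scaling, and the genes named from the reference mixtures, were chosen after the results had been seen. Intervals given from here on are 95% bootstrap intervals over genes, which are not independent. They do not measure the spread between cultures or libraries. The change from embryos to L1 larvae differed between the species, by a test of the difference itself, for 6299 of 12603 ortholog pairs. The named genes were ifa-3 (10.20), cut-2 (10.05), grd-14 (9.26), asp-15 (8.84) and abu-14 (8.49), with a higher change in C. elegans on the log2 scale, and pud-3 (-7.61), clec-50 (-7.06), ceh-75 (-7.05), srd-13 (-6.95) and nxnr-1 (-6.85), with a lower one. In C. elegans asp-15, ceh-75 and srd-13 lay below 1 RPKM in both stages, near the floor. Their differences therefore rest on the C. briggsae change, and the ortholog and gene model chosen are confounded with the species here too. The calls of cut-2 and abu-14 did not hold without some of the cultures, with adjusted p up to 0.0713 and 0.0552.

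Scaling did not account for the number of differing pairs, since 5871 still differed under quantile normalization. The split turned, though, from 4140 higher and 2159 lower changes in C. elegans to 2700 and 3171. Whether the same pairs differed was not checked, so scaling stays open for the direction of the difference. The tables argued against gene length, since the difference was unrelated to exon length (Spearman rho = -0.00124, interval -0.0194 to 0.0161, across 12343 of the pairs, 97.9%). A younger mix of embryos in the C. briggsae cultures stayed open: the embryo difference between species followed the difference between the C. briggsae cultures (Pearson r = 0.194, interval 0.176 to 0.213, across genes). Along that axis muscle (1.56) and pharynx (1.42) genes were higher in C. briggsae embryo library A2 than in B, while ribosomal protein genes were not apart (-0.05). Embryo age may therefore account for part of the muscle and pharynx difference, although that this axis reflects age was not tested. The ribosomal protein genes showed no difference along it. Most of their calls for the species difference were lost under median-ratio scaling, as given above. A species difference in embryonic expression was not tested separately and stays open.

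Ribosomal protein genes also lay below genes of matched length in embryos relative to L1 larvae, by a median of -1.66 in C. elegans (interval -2.02 to -1.44) and -2.35 in C. briggsae (-2.70 to -2.14), which argued against gene length as their cause.

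The reference mixtures, used in no comparison, held transcripts at 4 times the level of every stage library or more, for 48 of 7377 C. elegans and 43 of 6307 C. briggsae genes at 10 RPKM or more in both reference libraries. In C. elegans the neuropeptide-like gene nlp-39 stood at 83.6 and 132 RPKM against at most 0.659 in any stage library, the invertebrate lysozyme ilys-3 at 237 and 196 against 3.95, and the metallothionein mtl-2 at 673 and 741 against 18.2. In C. briggsae the lipase lipl-8 stood at 53.6 and 31.1 RPKM against 0.283, asp-18 at 39.9 and 55.7 against 0.633, and the collagen col-158 at 661 and 428 against 10.2. Many of the 43 C. briggsae genes were collagens, and the cuticlin cut-1 stood among them. Some of the 48 C. elegans genes were collagens too.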

How the results depend on the processing

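Leaving out library A1 of the C. elegans embryos, the embryo stage, the L3 stage or certain gene IDs was chosen after the results had been seen. Over the alternatives that kept all cultures, counts ran from 8536 to 12616 for C. elegans embryo versus L1, 7390 to 9541 for C. briggsae, 5447 to 7377 for the species difference, 4415 to 5192 for stage differences and 3542 to 4509 for species level (3429 and 5011 without the embryo stage), and matched-stage rho from 0.725 to 0.805. Leaving out a culture gave 7839 to 9105, 5122 to 8690 (5122 and 5286 without L1 culture A or B, where fewer genes were tested) and 4836 to 5883, and 9 to 13 and 11 to 13 list calls in C. elegans and C. briggsae; the lone culture is then assumed to vary like the other groups. With the culture as a replicate block the counts were 10769, 9053 and 6066, and the block changed no call of a list. L2 versus L1 had 3 calls with a pseudocount of 0.1 and 1 without the L3 stage, and young adult versus late L4 2332 without the embryo stage (1497 up and 835 down, against 854 and 218). With an estimated inter-gene correlation camera called 0 lists in C. elegans and 0 in C. briggsae, against 10 and 11 at adjusted p under 0.05 with the preset, and with quantile normalization the preset gave 10 and 14. The median profile r was 0.718 and 0.835 with pseudocounts of 0.1 and 5, 0.773 with cultures averaged and 0.829 for pairs with a range of at least 3. Apart from the camera calls, the cause was not tested for these last changes. Of the values of the named genes under the alternatives 2104 kept direction and call, 18 lost the call and 0 reversed. These genes were chosen for large called changes in the main fits, and the alternatives reuse the same libraries. Their counts therefore do not show how well calls of other genes hold. Depth, estimated for 1 library alone, limits low-abundance genes.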

Other observations

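The tests of molting phase, of vitellogenin RNA at L2 and of other splits of the samples were chosen after the results had been seen. Among argonautes, which bind small RNAs, wago-1 was highest in C. elegans young adults (262 RPKM) and C. briggsae embryos (74.4), while sago-2 reached 363 RPKM in C. briggsae embryos and at most 11.6 in any C. elegans stage. The muscle genes mlc-2 (2259 RPKM at L1) and pat-10 (2252 at L2) and the ribosomal protein genes rps-25 (5808 at L2) and rpl-39 (5218 at L2) held the highest C. elegans stage values of their lists. The neuropeptide-processing genes egl-21 and egl-3 stood at 475 ± 157 and 376 ± 110 RPKM in C. elegans L1 larvae and at 539 ± 83.0 and 390 ± 60.9 in C. briggsae (SD, n = 2 cultures).

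The L3 to L4 changes ran opposite ways in the species (r = -0.46 across genes, and -0.45 without the molting, collagen and pharynx lists). The values argued against a swap of the L3 and L4 labels in C. elegans. Genes that rose from L2 to late L4 in both species (255) also rose more from L3 to L4 than those that fell (601). The difference of medians was 0.584 (interval 0.460 to 0.719). In C. briggsae that difference was -0.269 (-0.340 to -0.155), so a swap there stays open. Each of these stages had 1 library per species, so neither interval covers the spread between libraries. Sampling at other phases of the molting cycle may also account for the pattern: the C. elegans L3 to L4 change followed the C. briggsae L2 to L3 change (r = 0.508, interval 0.485 to 0.529), although both C. briggsae steps share the L3 library. The L2 to L3 changes of the species did not correlate positively by Pearson r either (-0.09), and both readings involve that step. The C. elegans L2 to L3 change followed the C. briggsae L1 to L2 change (r = 0.487), a step that an L3 and L4 swap would not touch.

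The C. elegans L2 library held vitellogenin RNA, with vit-2 at 209 and vit-6 at 180.7 RPKM, a median of 1.87% of the young adult value over 6 genes, and the L3 library held less (32.97 and 31.37 RPKM). Material of the young adult library cannot be told apart as a source, because major sperm proteins held 0.229% of their young adult value, a ratio of 0.122 to the vitellogenin share that lies between the bounds set for either reading. The median share was 1.87% for oocyte and maternal factors (36 genes), 0.983% for spermatogenesis genes (6 genes) and 3.81% for germline genes (33 genes). Adults with oocytes or embryos among the L2 larvae are a candidate source: oocyte and maternal genes were higher at L2 than the mean of L1 and L3, although L3 held vitellogenin RNA too (median 0.76, interval 0.30 to 1.20; 31 of 37 above both), while in C. briggsae 4 of 32 were. Germline genes were not raised (-0.13). No biological explanation was tested.

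Of 100 splits of the 14 stage samples into 2 groups of 7, the real one included, 1 gave as many calls as the species level comparison (4262, against 2671 in the highest other split). These splits ignore that each stage has a sample of either species. Of the 64 splits that swap the species within stages, the real one again was the 1 with as many calls, and the highest other split gave 1012. A share of 1 in 64 is the smallest this test can give, so it does not exclude chance. The gene models and orthologs chosen in each species also follow the real split.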
